A study of Mus musculus with 4 samples.

How the data were processed

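RNA was extracted from sorted squamous cell carcinoma stem cells and made into libraries with an Illumina mRNA kit, per the labels' protocols. Samples were grouped by the reporter state in their titles into 2 reporter negative and 2 reporter positive libraries, and the titles also number the experiment (1 or 2). Nothing in the labels says whether the 2 experiments used separate animals, so p-values measure only the spread between these libraries.

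The authors aligned reads with TopHat and estimated transcript abundance with Cufflinks on mouse build mm9, per the submitters' processing notes; versions are not given in the sources used here. The deposited files are Cufflinks transcript tables, and they hold for each transcript an FPKM value (fragments scaled to transcript length and library depth), its confidence interval and its read coverage, per the file headers. They list Ensembl transcripts beside transcripts assembled from the reads, so assembly was guided by an annotation, whose release is not given in the sources used here. FPKM is already divided by depth and length, so no count model was used. Assembly differs between libraries, and reads given to an assembled form in 1 library can lie on an annotated form in another.

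Genes were rebuilt from the transcripts with Python 3.11.15 and pandas 2.3.3. The files replace gene identifiers by locus numbers wherever reads were found, so of 96734 reference transcripts 84047 were named by transcript identifier through GENCODE M21, used for names only because it describes another build, and 5138 through the gene identifier in the files. The other 7549 and all assembled transcripts went to the gene whose exons on the same strand held most of their length, if at least 50% lay there. Of the summed FPKM, 12% to 13.6% was placed in this way. Transcripts under 200 exonic bases were left out. They carried 95.1% to 98.9% of all FPKM, and only 10.8% to 15.5% of those above 0 lay inside their own interval, against 94.6% to 95% of longer ones. Named genes then held 87.3% to 90.1% of the remaining FPKM. Coordinates are those of the files (mm9). Mitochondrial genes, and list members without a value, keratins among them, were not analysed here.

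Depth was recovered from the files as the ratio of coverage to FPKM, which gives aligned bases. Read length is not given in the sources used here, so the number of reads is unknown. The distance from the centre of a gene's interval to its bounds was 15.5% to 16.9% of the value (median over genes) at 1 to 5 FPKM and 3.25% to 3.55% above 100 FPKM, which covers counting error only. Among genes tested, 469 were listed at exactly 0 in at least 1 library, including genes that every cell uses. Such a 0 can be a failed estimate, so these genes were kept in the test as deposited, are described only as listed at 0, and were left out in an alternative.

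Genes with at least 1 FPKM in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(FPKM + 1), positive against negative, two-sided, with Benjamini-Hochberg adjustment over the 11973 genes and a threshold of 0.05. An exact permutation test of 2 against 2 libraries cannot go below 0.333, so none was used. On simulated data with these genes, means and spreads, in 5 draws, the test recovered 1.2% of 2-fold and 36.8% of 4-fold changes, with 1.4 false calls on average and at most 2, and none of the wrong sign. Fewer genes were changed in those draws than the 646 that passed in the data, and recovery and false calls depend on that number. These rates may therefore not carry over to the data. Changes near 2-fold that did not pass are not shown to be absent. Gene lists were tested with camera at a preset correlation of 0.01, which sets a list against all other genes, with Benjamini-Hochberg adjustment over the 33 of 41 lists that had at least 5 tested genes. Each call was recomputed with an estimated correlation and with fry, which tests a list without reference to other genes. With 2 libraries per group both rest on few degrees of freedom, and what they can find was not simulated. Lists of leukocytes, T and NK cells, melanocytes, skeletal muscle, erythrocytes, sebocytes, sex-linked and mitochondrial genes had fewer than 5 tested genes. Agreement between experiments was described by correlations across genes and by shared genes at least 2-fold apart, against the product of the 2 list sizes over the number of genes.

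Named genes followed a rule: the 8 largest rises and 8 largest falls among genes past the threshold, changed the same way in both experiments and with a mean of at least 5 FPKM in the higher group, without unnamed models, pseudogenes or ribosomal proteins; up to 4 members with the smallest p of each list described; and Itga6, Cd44, Tgfbr1, Tgfbr2, Hras, Cdkn1a, Nfe2l2 and Hmga2 whatever their values. The rule, the lists, the tests and most alternatives were fixed before the data were examined. After the values were seen the rule was applied a second time to genes above 0 in every library, and Col1a1 and Jund were named. The experiment number in the titles was taken to pair the libraries: deviations of same-numbered libraries from their group means correlated with r 0.172 across genes, and 0.31 across genes above 0 in every library. Pairing the libraries the other way would give the same r with its sign changed, so these values do not settle the pairing, which rests on the titles. The fit with the experiments as a block is given beside results it changes. It leaves fewer residual degrees of freedom than the fit by group alone.

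Alternatives fixed before the data were examined were the block, pseudocounts of 0.1 and 5, no filter and a minimum of 5 FPKM, rescaling to a common sum (TPM), median-of-ratios and quantile scaling, eBayes without trend or with robust estimation, the most abundant transcript per gene, and each library left out. Added after seeing the data were genes listed at 0 left out (alone and with the block), reference transcripts only, and a minimum of 300 bases. Figures were drawn with matplotlib 3.10.9.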

Results

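Messenger RNA was sequenced from stem cells of primary mouse skin squamous cell carcinomas. The tumours came from epidermis and carried an inducible Hras transgene, an oncogenic driver of skin tumours, and a fluorescent reporter that reads out transforming growth factor beta (TGF-β) signalling as mCherry. Cells were depleted of other lineages, selected by the surface proteins integrin α6 and CD44, and sorted into reporter positive and reporter negative fractions in 2 experiments. Each fraction gave 1 library per experiment, so each group held n = 2. Aligned bases recovered from the files came to 3.21 and 3.83 gigabases in the reporter negative libraries of experiments 1 and 2, and to 3.63 and 3.36 gigabases in the reporter positive ones. Values below are FPKM, given as mean ± SD over the 2 libraries of a group, reporter negative first. Changes are positive minus negative on the log2(FPKM + 1) scale, ± SE, which understates the change of low genes.

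The comparison asked how tumour stem cells with TGF-β signalling differed in gene expression from those without it. At a preset correlation between genes, the lists of keratinocyte differentiation, cell junctions, RAS and EGFR feedback and sterol synthesis were higher in reporter positive cells, and those of DNA replication, basal keratinocytes and Wnt signalling lower. None of these list calls held with an estimated correlation (adjusted p = 0.453 to 0.672) or with fry, and in the basal list 1 of 14 genes passed. Of 11973 genes tested with limma, 646 passed an adjusted p of 0.05, with 321 higher and 325 lower in reporter positive cells. An unadjusted p under 0.05 was found for 3094 genes. Of the 646 genes, 562 were above 0 in every library, 279 higher and 283 lower. With the 2 experiments as blocks, 1422 genes passed (533 higher, 889 lower), the 646 among them. Once genes listed at 0 in any library were left out 1262 passed without blocks, and 3322 with them. The deposited values put the median change of all tested genes at -0.18, and median-of-ratios scaling put it at 0.01. The split was then 424 higher and 200 lower, and with quantile normalization it was 422 and 256. With robust variance estimation 1002 genes passed, with no filter on low values 4, with the most abundant transcript per gene 62 and with reference transcripts only 71. Each library weighed on the count: 191 genes passed without reporter negative replicate 1, 3 without reporter negative replicate 2, 86 without reporter positive replicate 1 and 52 without reporter positive replicate 2. In those fits the lone library of a group was taken to vary like the other group, and every one of the 646 genes kept its sign in each of the 4. The 646 were chosen from these same libraries, which makes a kept sign likely, so it adds no support. In the same order 120, 1, 58 and 32 of the 646 still passed, so the calls of single genes below are those made with all 4 libraries.

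The changes of the 2 experiments, which share no library, went together across genes. Across 11973 genes the differences correlated with Pearson's r 0.524 and Spearman's rho 0.624. Across the 11504 genes above 0 in every library these were 0.736 and 0.661, and genes are not independent replicates. At least 2-fold higher in both experiments were 310 genes, where independent lists would share 25.4, and at least 2-fold lower in both were 371, where they would share 50.2. Opposite changes of that size were seen in 72 genes. The difference between experiments 2 and 1, taken in the same way in each fraction, gave r 0.172 and rho 0.378. In that comparison 34 genes were up in both fractions, where independent lists would share 4.7, 65 were down, where they would share 4.8, and 66 were opposite. Libraries of one fraction also resembled each other more (r 0.978 between the negative and 0.987 between the positive libraries) than libraries across fractions (0.944 to 0.96).

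**Figure D1:**
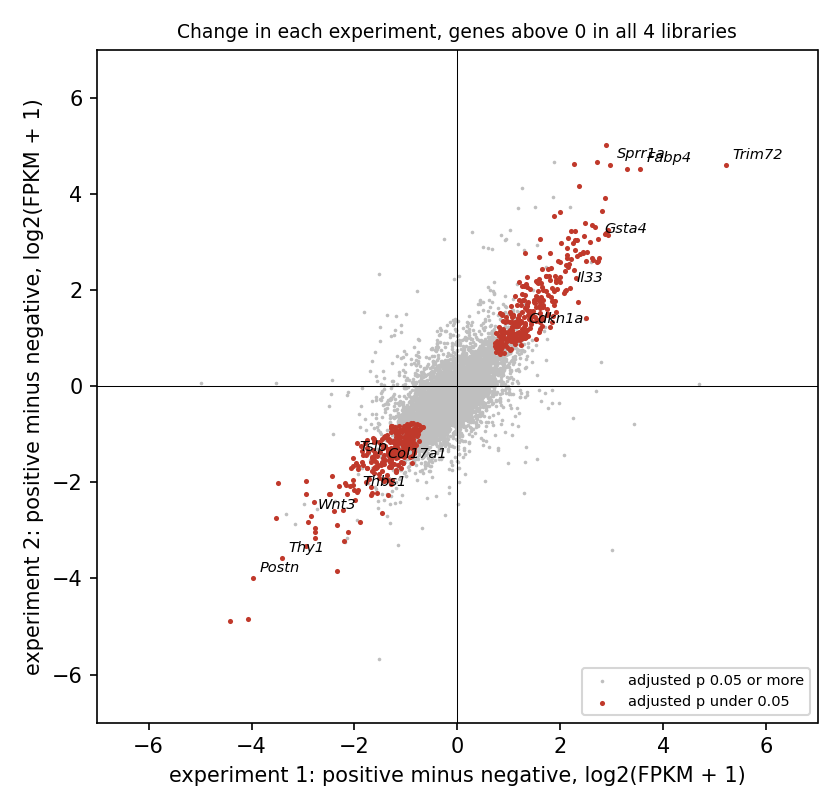
Each point is a gene above 0 in all 4 libraries, with its positive minus negative difference on the log2(FPKM + 1) scale in experiment 1 (horizontal) and in experiment 2 (vertical). Red points had an adjusted p under 0.05 in limma. They lie along the diagonal, which the choice of genes by these same differences favours. Over all points drawn, red and grey, r was 0.736.

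Among genes above 0 in every library, the largest rise was that of Trim72 (ENSMUSG00000042828, chromosome 7, 135147503 to 135154907), which encodes a membrane repair protein, at 0.341 ± 0.0676 against 40.1 ± 10.3 FPKM (log2 fold change 4.92 ± 0.24, adjusted p = 0.00442). Next came Fabp4, a fatty acid binding protein (88 ± 73.5 against 1254 ± 562 FPKM), the late cornified envelope gene Lce3c (15.3 ± 13.6 against 204 ± 18.7 FPKM), the barrier lipoxygenase Alox12b (3.69 ± 2.55 against 64.2 ± 1.78 FPKM) and the cornified envelope precursor Sprr1a (193 ± 146 against 2270.2 ± 86.1 FPKM). Cornifelin (Cnfn), the secreted protease inhibitor Slpi and the exonuclease Trex2 completed the 8, with log2 fold changes of 3.69, 3.44 and 3.4. The largest fall was that of Fcgbp (ENSMUSG00000047730, chromosome 7, 28856255 to 28905881), which encodes a mucin-like protein that binds immunoglobulin, at 106 ± 5.84 against 3.34 ± 1.2 FPKM (log2 fold change -4.65 ± 0.23, adjusted p = 0.00442). It was followed by Clca3a2 (73.6 ± 54.2 against 2.03 ± 1.24 FPKM), the matrix protein periostin, Postn (140.3 ± 71.6 against 7.88 ± 4.39 FPKM), and the surface glycoprotein Thy1 (23.9 ± 12.2 against 1.16 ± 0.905 FPKM). Epb41l3, the carboxypeptidase Scpep1, the guanylin gene Guca2a and the skin chemokine Ccl27a fell by 3.13, 3.13, 2.96 and 2.90 on the log2 scale. Their adjusted p lay between 0.00442 and 0.0498. Lce3c and Sprr1a have close relatives in one gene cluster, so the division of reads among family members is uncertain.

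By the same rule without the condition on zeros, 13 further genes were named, each listed at 0 in at least 1 library. Stfa1, a stefin with near-identical neighbours, stood at 2334 and 1899.6 FPKM in the reporter negative and 0 and 0 FPKM in the reporter positive libraries. Ptges, the prostaglandin E synthase, was listed at 0 and 0 FPKM in the reporter negative and 114 and 139 FPKM in the reporter positive libraries. Also listed at 0 in both reporter negative libraries were Jmjd6 (50.3 and 56.5 FPKM in the positive ones), the sterol-related thiolase Acat2 (49.6 and 55.4), Eif2b4 (25.6 and 31.7), Srd5a1 (21.1 and 25.7) and Bicdl2 (17.5 and 18.4). Lce3d stood at 0 and 1.78 against 70.3 and 92.2 FPKM. Listed at 0 in both reporter positive libraries were Erap1 (15.5 and 20.4 FPKM in the negative ones), Ppp2r3c (16.6 and 16.4), Hmces (15.1 and 15.4), Psmc3ip (15.7 and 14.8) and Ifi35 (16.3 and 13.7). The files mark at least 1 transcript of the gene as fully covered by reads in every library at 0 for Stfa1, Ptges, Jmjd6, Acat2, Lce3d, Eif2b4, Srd5a1, Hmces, Psmc3ip and Ifi35. No fold change is given for these genes.

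Genes of the sort itself and of the TGF-β pathway were examined as a check of the labels. Itga6, which encodes integrin α6 of the gate, was at 371 ± 56 against 193 ± 16.9 FPKM (adjusted p = 0.0548, and 0.0156 with the experiments as blocks), and Cd44 at 96.9 ± 21.8 against 108 ± 28.3 FPKM (adjusted p = 0.759). Of the 26 TGF-β/Smad target genes tested, 1 was higher, 3 were lower and 22 did not pass. Adjusted over the list alone, the counts were 1 higher and 9 lower, and with the experiments as blocks 1 and 7. The cell cycle inhibitor Cdkn1a was the target that rose, from 54.3 ± 2.42 to 128 ± 1.52 FPKM (log2 fold change 1.23 ± 0.13, adjusted p = 0.0179). Thrombospondin (Thbs1) fell from 34.2 ± 9.73 to 7.22 ± 1.31, the matrix protein gene Tgfbi from 350.1 ± 24.4 to 164 ± 17.3, and Ccn2 from 4.57 ± 0.952 to 0.685 ± 0.331 FPKM. The list as a whole did not pass (median -0.5, camera adjusted p = 0.205), and 16 members were lower and 5 higher in both experiments. The list median was -0.325 without reporter positive replicate 1, -0.316 with median-of-ratios scaling and -0.314 with quantile normalization. Hmga2, an architectural chromatin protein in that list, was at 17.6 ± 2.46 against 20.4 ± 4.46 FPKM (adjusted p = 0.619).

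TGF-β ligands, receptors and activators were lower as a group in reporter positive cells (median log2 fold change -0.58, camera adjusted p = 0.0187 and adjusted p = 0.674 with an estimated correlation). Of 19 members, 0 were higher, 2 were lower and 17 did not pass. The counts were 0 higher and 5 lower adjusted over the list alone, and 0 and 4 with the experiments as blocks. The ligand gene Tgfb3 fell from 11.8 ± 2.5 to 3.73 ± 0.0512 FPKM. The other of the 2, the activin subunit Inhba, was listed at 1.83 and 2.28 FPKM in the reporter negative libraries. It was listed at 0 and 0 FPKM in the reporter positive ones, with a transcript marked as fully covered by reads in 1 of them. Tgfb2 was at 2.34 ± 0.118 against 0.72 ± 0.165 FPKM (adjusted p = 0.0664, and 0.048 with blocks) and the latency protein gene Ltbp1 at 18.1 ± 2.15 against 10.4 ± 0.114 FPKM, neither past the threshold. The receptors Tgfbr1 (6.51 ± 1.73 against 4.72 ± 0.947 FPKM, adjusted p = 0.397) and Tgfbr2 (17.4 ± 11 against 10.6 ± 4.48 FPKM, adjusted p = 0.523) did not pass. The list's call was lost without reporter negative replicate 2 (median -0.24, adjusted p = 0.153) and without reporter positive replicate 1 (-0.38, 0.108). It was also lost with a minimum FPKM of 5 (0.0699), with reference transcripts only (0.123) and with the most abundant transcript per gene (0.171).

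Genes of keratinocyte differentiation were higher in reporter positive cells (median log2 fold change 2.45, camera adjusted p = 1.95e-12 and adjusted p = 0.453 with an estimated correlation). Of 19 members, 10 were higher, 1 was lower and 8 did not pass. Within the list alone, adjustment gave 14 higher and 1 lower, and the blocked fit gave 13 and 1. The transglutaminases that cross-link the cornified envelope rose, Tgm1 from 9.48 ± 1.48 to 71.6 ± 4.81 and Tgm3 from 102 ± 12.7 to 638 ± 74.5 FPKM, with log2 fold changes of 2.8 ± 0.17 and 2.63 ± 0.17. Grhl3, a transcription factor of the epidermal barrier, rose from 9.55 ± 0.402 to 55.5 ± 12.7 FPKM. The member counted as lower, the desmocollin Dsc1, was listed at 4.57 and 6.41 FPKM in the reporter negative libraries. In both reporter positive libraries it was listed at 0 with a transcript marked as fully covered by reads, so this call can rest on failed estimates. Wound and hyperproliferation genes were higher too (median log2 fold change 1.99, camera adjusted p = 5.50e-04 and adjusted p = 0.672 with an estimated correlation). Among 11, 3 were higher, 2 were lower and 6 did not pass. With adjustment over the list alone 7 rose and 2 fell, and with experiments as blocks 6 and 2. The antimicrobial peptide gene Defb14 rose from 34.2 ± 21.5 to 309.5 ± 70.9 FPKM and Slpi from 85.3 ± 66.9 to 799 ± 228, whereas lipocalin (Lcn2) fell from 5.9 ± 0.946 to 1.28 ± 0.26. The remaining pair of calls, Stfa1 and S100a7a, rest on values listed at 0. This list's median, mean (0.53) and camera test were upward, while the fry test put its direction down (adjusted p = 0.169). Stfa1, listed at 0 in both reporter positive libraries, had the smallest unadjusted limma p of the list (1.58e-08). The fry test was not run without Stfa1. Without reporter negative replicate 2 the median of the list was 0.93.

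Junction genes were higher as a group (median log2 fold change 0.48, camera adjusted p = 2.05e-06 and adjusted p = 0.672 with an estimated correlation). Of 21, 5 were higher, 0 were lower and 16 did not pass. The blocked fit gave 8 higher and 2 lower, and adjustment over the list alone 8 and 2. The desmosomal cadherin Dsc2 rose from 28 ± 0.249 to 167 ± 32.8 FPKM, the tight junction gene Cldn4 from 3.96 ± 0.704 to 25.9 ± 4.25, the polarity gene Crb3 from 11.6 ± 0.772 to 38.6 ± 2.21, and the epithelial splicing factor Esrp2 from 32 ± 1.91 to 57.1 ± 1.77. Without reporter negative replicate 1 the junction median was 0.28. Basal keratinocyte and hemidesmosome genes were lower (median log2 fold change -0.57, camera adjusted p = 0.0282 and adjusted p = 0.672 with an estimated correlation). Of 14, 0 were higher, 1 was lower and 13 did not pass. Adjusted over the list alone, the counts were 1 higher and 7 lower, and with the experiments as blocks 0 and 6. Col17a1, the hemidesmosomal collagen, fell from 749 ± 36.9 to 254 ± 6.35 FPKM (log2 fold change -1.55 ± 0.15, adjusted p = 0.0165), and the integrin genes Itgb4 (102 ± 20.1 against 56.5 ± 3.42 FPKM) and Itga3 (91.8 ± 2.96 against 61.3 ± 5.98 FPKM) did not pass. With blocks the adjusted p of Itgb4 was 0.0278. The basal list lost its call without reporter negative replicate 1 (adjusted p = 0.0772) and without reporter positive replicate 1 (0.138). Among 10 hair follicle stem cell genes, 0 were higher, 2 were lower and 8 did not pass. The counts were 0 higher and 4 lower adjusted over the list alone, and 0 and 2 with the experiments as blocks. The 2 were Postn and the transcription factor Lhx2 (1.7 ± 0.215 against 0.204 ± 0.111 FPKM). Fibroblasts stay open below as a part of the source of Postn, and the list was not tested without that gene. The list as a whole did not pass (median -0.56, camera adjusted p = 0.103). It passed with median-of-ratios scaling (adjusted p = 0.0368), with no filter on low values (0.015) and with blocks once genes listed at 0 were left out (0.0407). It did not with an estimated correlation (adjusted p = 0.672) or with fry (0.0903).

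**Figure D2:**
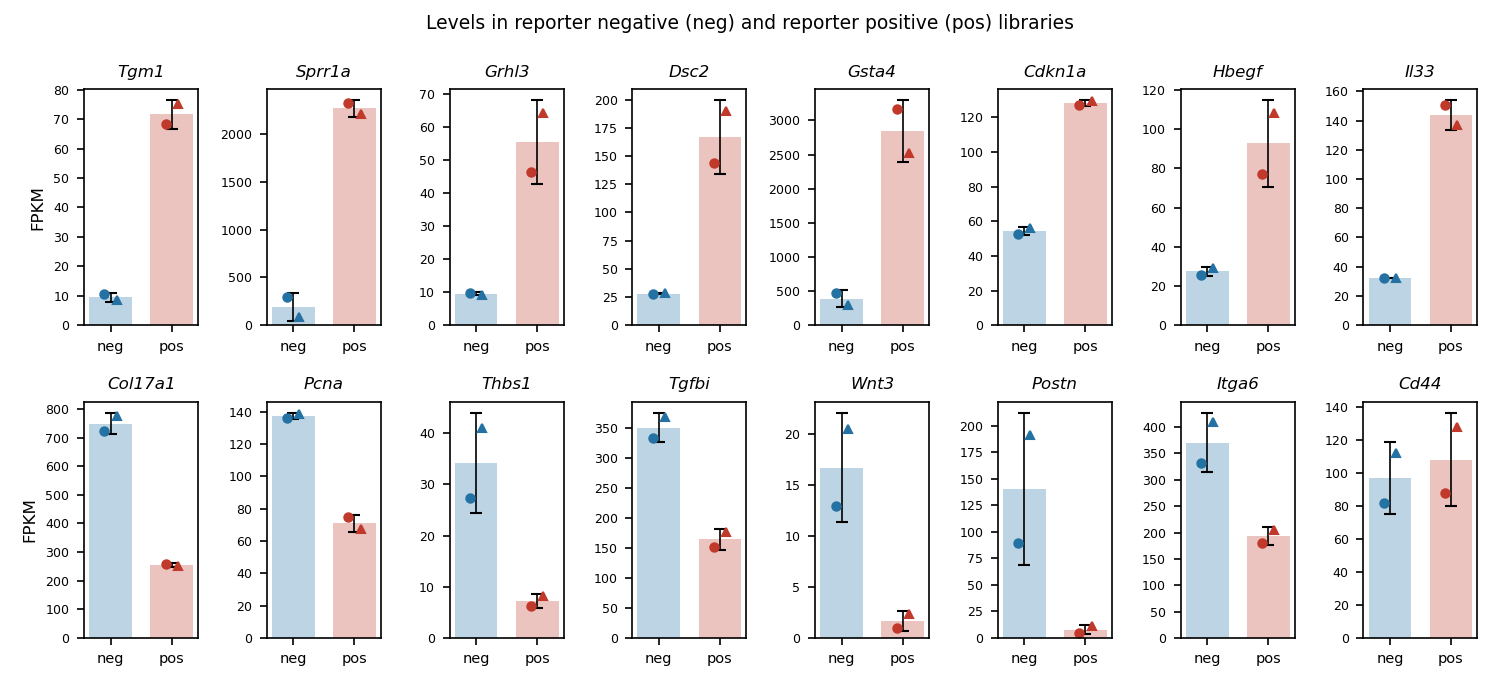
FPKM of 16 named genes in the reporter negative (blue) and reporter positive (red) libraries; bars are means, error bars SD over the 2 libraries, circles experiment 1 and triangles experiment 2. Both positive values lie above both negative ones for the 8 genes of the upper row and below them for the first 7 of the lower row, and the values of Cd44 overlap.

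Replication genes were lower in reporter positive cells (median log2 fold change -0.83, camera adjusted p = 3.39e-08 and adjusted p = 0.672 with an estimated correlation). Of 28 members, 0 were higher, 6 were lower and 22 did not pass. Within the list alone, adjustment gave 0 higher and 22 lower, and the blocked fit gave 0 and 14. In both experiments 27 were lower. The sliding clamp gene Pcna fell from 138 ± 1.71 to 71 ± 5.24 FPKM (log2 fold change -0.95 ± 0.13, adjusted p = 0.0336), the uracil glycosylase Ung from 17 ± 0.273 to 4.94 ± 0.979, the histone mRNA binding protein Slbp from 33.8 ± 2.91 to 15 ± 0.233, and the clamp loader subunit Rfc3 from 33 ± 1.66 to 14.6 ± 1.21. Mitotic genes were lower by a smaller median (median log2 fold change -0.5, camera adjusted p = 1.55e-04 and adjusted p = 0.672 with an estimated correlation). Of 35, 0 were higher, 1 was lower and 34 did not pass. With adjustment over the list alone 0 rose and 1 fell, and with experiments as blocks 0 and 5. In both experiments 31 were lower. Cyclin B2 (Ccnb2) fell from 47 ± 1.78 to 24.7 ± 0.421 FPKM, and Mki67 was at 37.9 ± 11.9 against 17 ± 0.467 FPKM without passing (adjusted p = 0.0777, and 0.0406 with blocks). Among 16 inhibitor and quiescence genes, 1 was higher, 1 was lower and 14 did not pass. The blocked fit gave 1 higher and 3 lower, and adjustment over the list alone 2 and 6. Cdkn1a was the higher one and Cdkn1b the lower (19.6 ± 0.394 against 9.83 ± 0.111 FPKM). The list median of -0.13 did not pass (adjusted p = 0.685) and changed sign with median-of-ratios scaling. It was -0.277 without reporter negative replicate 1, 0.073 without negative 2, -0.018 without positive 1 and -0.322 without positive 2. Targets of p53 were higher as a group (median log2 fold change 0.23, camera adjusted p = 0.00461 and adjusted p = 0.672 with an estimated correlation). Of 20, 2 were higher, 1 was lower and 17 did not pass. Adjusted over the list alone, the counts were 4 higher and 1 lower, and with the experiments as blocks 4 and 1. Those past the threshold were Cdkn1a and the kinase Plk2, which rose from 37.5 ± 5.15 to 71.9 ± 5.02 FPKM, and the death receptor gene Fas, which fell from 4.44 ± 0.51 to 1.29 ± 0.0729. The p53 median was 0.02 without reporter negative replicate 1 and 0.09 without reporter positive replicate 2.

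NRF2 targets and glutathione genes moved both ways with an upward balance (median log2 fold change 0.18, camera adjusted p = 1.55e-04 and adjusted p = 0.453 with an estimated correlation). Of 39 members, 7 were higher, 1 was lower and 31 did not pass. The counts were 13 higher and 5 lower adjusted over the list alone, and 12 and 5 with the experiments as blocks. The glutathione transferase Gsta4 rose from 389 ± 124 to 2840.5 ± 455 FPKM (log2 fold change 2.89 ± 0.29, adjusted p = 0.0179), sulfiredoxin (Srxn1) from 20.2 ± 0.499 to 53.9 ± 4.9 and the glutathione peroxidase Gpx2 from 75 ± 5.02 to 173 ± 8.58. Gstm2, a transferase of another class, fell from 42.9 ± 3.14 to 10.6 ± 2.35 FPKM, and Nfe2l2, the gene of NRF2, was at 127 ± 0.314 against 160.0 ± 20 FPKM (adjusted p = 0.249). Without reporter negative replicate 1 the median of the list was 0.3. Transferase genes have close paralogs, so the division of reads among them is uncertain. Of 11 efflux and aldehyde dehydrogenase genes, 1 was higher, 1 was lower and 9 did not pass. Within the list alone, adjustment gave 1 higher and 2 lower, and the blocked fit gave 1 and 3. Aldh1a3 rose from 5.35 ± 0.74 to 12.7 ± 0.142 and the transporter Abcg2 fell from 24.5 ± 8.1 to 5.72 ± 0.819 FPKM. That list did not pass (median -0.29, adjusted p = 0.723). Its median was -0.759 without reporter negative replicate 1, -0.065 without negative 2, -0.169 without positive 1 and -0.63 without positive 2.

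Sterol and fatty acid synthesis genes were higher (median log2 fold change 0.64, camera adjusted p = 7.37e-09 and adjusted p = 0.453 with an estimated correlation). Of 22 members, 3 were higher, 0 were lower and 19 did not pass. With adjustment over the list alone 10 rose and 1 fell, and with experiments as blocks 9 and 1. Lanosterol synthase (Lss) rose from 13.6 ± 0.641 to 34.2 ± 1.33 FPKM, farnesyl diphosphate synthase (Fdps) from 41.9 ± 3.2 to 88.7 ± 1.6 and the isomerase Idi1 from 26.5 ± 3.01 to 53.6 ± 3.51. The regulator Insig1 was at 13.1 ± 2.77 against 30.6 ± 5.37 FPKM (adjusted p = 0.0548, and 0.0164 with blocks). Hypoxia and glycolysis genes passed as a list (median log2 fold change 0.16, camera adjusted p = 0.00461 and adjusted p = 0.672 with an estimated correlation). Of its 27 members, 0 were higher, 0 were lower and 27 did not pass. The blocked fit gave 0 higher and 2 lower, and adjustment over the list alone 0 and 0. The 2 lower with blocks were Car12 (105 ± 15.1 against 64.2 ± 8.22 FPKM, adjusted p = 0.0283) and P4ha1 (21.2 ± 3.25 against 12.3 ± 3.19 FPKM, adjusted p = 0.0451). Vegfa was at 22.2 ± 0.566 against 42.9 ± 13.6 FPKM and the glucose transporter Slc2a1 at 408 ± 47 against 273 ± 15.8 FPKM. In both experiments 13 members of the list were higher and 7 lower. That call was lost without reporter negative replicate 2 (median 0.06, adjusted p = 0.0819) and without reporter positive replicate 2 (0.1, 0.194). The median was 0.29 without reporter negative replicate 1 and 0.33 without reporter positive replicate 1. Oxidative phosphorylation genes (24 tested, none past the threshold singly) had a median of -0.29 and camera adjusted p = 0.0531, which became 0.0181 with blocks (where 1 gene was lower). It was 0.0109 without reporter negative replicate 2 and 0.043 without reporter positive replicate 1. It also passed with no filter (0.00679), TPM (0.014), quantile normalization (0.00506), the most abundant transcript (0.0494) and reference transcripts only (0.0466). It did not with an estimated correlation (adjusted p = 0.674) or with fry (0.136).

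Ligands and feedback genes of the epidermal growth factor receptor and RAS pathway were higher (median log2 fold change 0.45, camera adjusted p = 4.50e-05 and adjusted p = 0.555 with an estimated correlation). Of 21, 4 were higher, 0 were lower and 17 did not pass. Adjusted over the list alone, the counts were 9 higher and 1 lower, and with the experiments as blocks 6 and 1. The receptor ligands Hbegf and Ereg rose from 27.5 ± 2.41 to 92.8 ± 22.1 and from 3.8 ± 0.569 to 12.3 ± 1.53 FPKM, Phlda1 from 20.1 ± 2.72 to 47.5 ± 3.31, and the phosphatase Dusp5 from 6.62 ± 0.113 to 13.2 ± 0.132. The annotated mouse gene Hras was at 201 ± 12.9 against 191 ± 23 FPKM (adjusted p = 0.804), with a direction that flipped under median-of-ratios scaling. Whether reads of the inducible Hras transgene are counted there was not tested. The median of the RAS list was 0.27 without reporter positive replicate 2. Wnt genes were lower (median log2 fold change -0.77, camera adjusted p = 0.00461 and adjusted p = 0.672 with an estimated correlation). Of 15, 0 were higher, 3 were lower and 12 did not pass. The counts were 0 higher and 10 lower adjusted over the list alone, and 0 and 6 with the experiments as blocks. The ligand genes Wnt10a and Wnt3 fell from 72.4 ± 16 to 21.8 ± 0.766 and from 16.7 ± 5.34 to 1.64 ± 0.975 FPKM, and the pathway target Axin2 from 5.11 ± 0.982 to 1.36 ± 0.324. The Wnt list lost its call with the most abundant transcript per gene (adjusted p = 0.0817) and with reference transcripts only (0.0607). In the Notch list of 9, 1 was higher, 2 were lower and 6 did not pass. Within the list alone, adjustment gave 1 higher and 4 lower, and the blocked fit gave 1 and 3. The target Nrarp rose from 41.2 ± 2.17 to 104 ± 5.72 FPKM while the ligand genes Jag2 and Dll1 fell from 56.3 ± 15.9 to 15.2 ± 2.72 and from 11.6 ± 0.837 to 4.67 ± 0.351. Of 5 BMP targets, 0 were higher, 1 was lower and 4 did not pass. With adjustment over the list alone 1 rose and 1 fell, and with experiments as blocks 1 and 2. The lower one was Id3 (36.6 ± 0.774 against 17.8 ± 0.257 FPKM). Neither the Notch nor the BMP list passed (medians -0.44 and -0.41, camera adjusted p = 0.847 and 0.69). The BMP median was -0.194 without reporter positive replicate 1 and -0.652 without reporter positive replicate 2.

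Cytokine genes went both ways. Of 21 tested, 2 were higher, 1 was lower and 18 did not pass. The blocked fit gave 2 higher and 2 lower, and adjustment over the list alone 3 and 2. The list did not pass (median 0.09, camera adjusted p = 0.0963), and without reporter positive replicate 1 its median was 0.207 and its adjusted p 0.0277. With an estimated correlation over all 4 libraries the adjusted p was 0.672, and with fry 0.589. The median was 0.216 without reporter negative replicate 1, -0.019 without negative 2 and -0.082 without positive 2. The alarmin Il33 rose from 32.5 ± 0.143 to 144 ± 10 FPKM (log2 fold change 2.11 ± 0.13, adjusted p = 0.00792) and the prostaglandin synthase Ptgs2 from 8.63 ± 0.255 to 24.2 ± 7.15, and Tslp fell from 125 ± 20.1 to 36.1 ± 3.85. Interferon response genes were lower as a list (median log2 fold change -1.0, camera adjusted p = 4.50e-05 and adjusted p = 0.672 with an estimated correlation), and 15 of 16 were lower in both experiments. Singly, 0 were higher, 2 were lower and 14 did not pass. Adjusted over the list alone, the counts were 0 higher and 11 lower, and with the experiments as blocks 0 and 6. Both of the lower ones, Ifi35 and Psmb9, were listed at 0 in the reporter positive libraries. For each, a transcript is marked as fully covered by reads in both of those libraries, so these calls can rest on failed estimates. Psmb8, an immunoproteasome subunit, was at 24.2 ± 9.17 against 5.92 ± 2.85 FPKM and the chemokine Cxcl10 at 3.37 ± 0.0376 against 0.873 ± 0.417 FPKM, neither past the threshold. With blocks their adjusted p was 0.009 and 0.0369.

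Genes of the mesenchymal programme were lower in reporter positive cells (median log2 fold change -0.81, camera adjusted p = 0.0217 and adjusted p = 0.672 with an estimated correlation). Of 10 members, 0 were higher, 1 was lower and 9 did not pass. The counts were 0 higher and 6 lower adjusted over the list alone, and 0 and 6 with the experiments as blocks. Smooth muscle actin (Acta2) fell from 24.2 ± 2.15 to 11 ± 0.0248 FPKM, and the transcription factor Snai2 was at 37.2 ± 9.22 against 18.2 ± 1.21 FPKM without passing (adjusted p = 0.0717, and 0.0286 with blocks). Fibroblast markers moved with them (median log2 fold change -0.71, camera adjusted p = 0.0217 and adjusted p = 0.672 with an estimated correlation). Of 13, 0 were higher, 1 was lower and 12 did not pass. Within the list alone, adjustment gave 0 higher and 2 lower, and the blocked fit gave 0 and 3. The lower one was Thy1. Collagen I, the most abundant product of fibroblasts, was low in both groups, Col1a1 at 8.79 ± 1.73 against 4.85 ± 1.59 FPKM. The fibroblast call was lost without reporter negative replicate 2 (median -0.49, adjusted p = 0.0819) and without reporter positive replicate 1 (-0.44, 0.166). It was lost as well with reference transcripts only (0.199) and with the most abundant transcript (0.171). Other cell type lists did not pass: pericyte and smooth muscle genes had a median of -0.72 (1 of 5 lower, Acta2, 3 adjusted over the list alone, 2 with blocks, adjusted p = 0.205). Endothelial genes had -0.8 (0 of 5, 3 lower adjusted over the list alone, 1 with blocks, adjusted p = 0.298) and macrophage and dendritic cell genes 0.06 (mean -0.24; 0 of 10; 3 lower with blocks; 0.623). With no filter on low values these 3 lists passed, the pericyte list at a median of -0.195 (adjusted p = 0.00812), the endothelial one at -0.801 (0.0338) and the macrophage one, on the other side of 0, at 0.165 (0.0331). With an estimated correlation their adjusted p was 0.672, 0.672 and 0.951, and with fry 0.0863, 0.0905 and 0.955. The macrophage median was 0.026 without reporter negative replicate 1, 0.031 without negative 2, 0.551 without positive 1 and -0.441 without positive 2. Its 3 genes lower with blocks were Cd74 (33.8 ± 11.6 against 12.9 ± 6.42 FPKM), H2-Eb1 (16 ± 4.31 against 6.65 ± 2.5) and H2-Ab1 (18.5 ± 4.71 against 8.36 ± 3.64). With blocks 0 of its genes were higher, and without blocks none of the 3 passed.

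**Figure D3:**
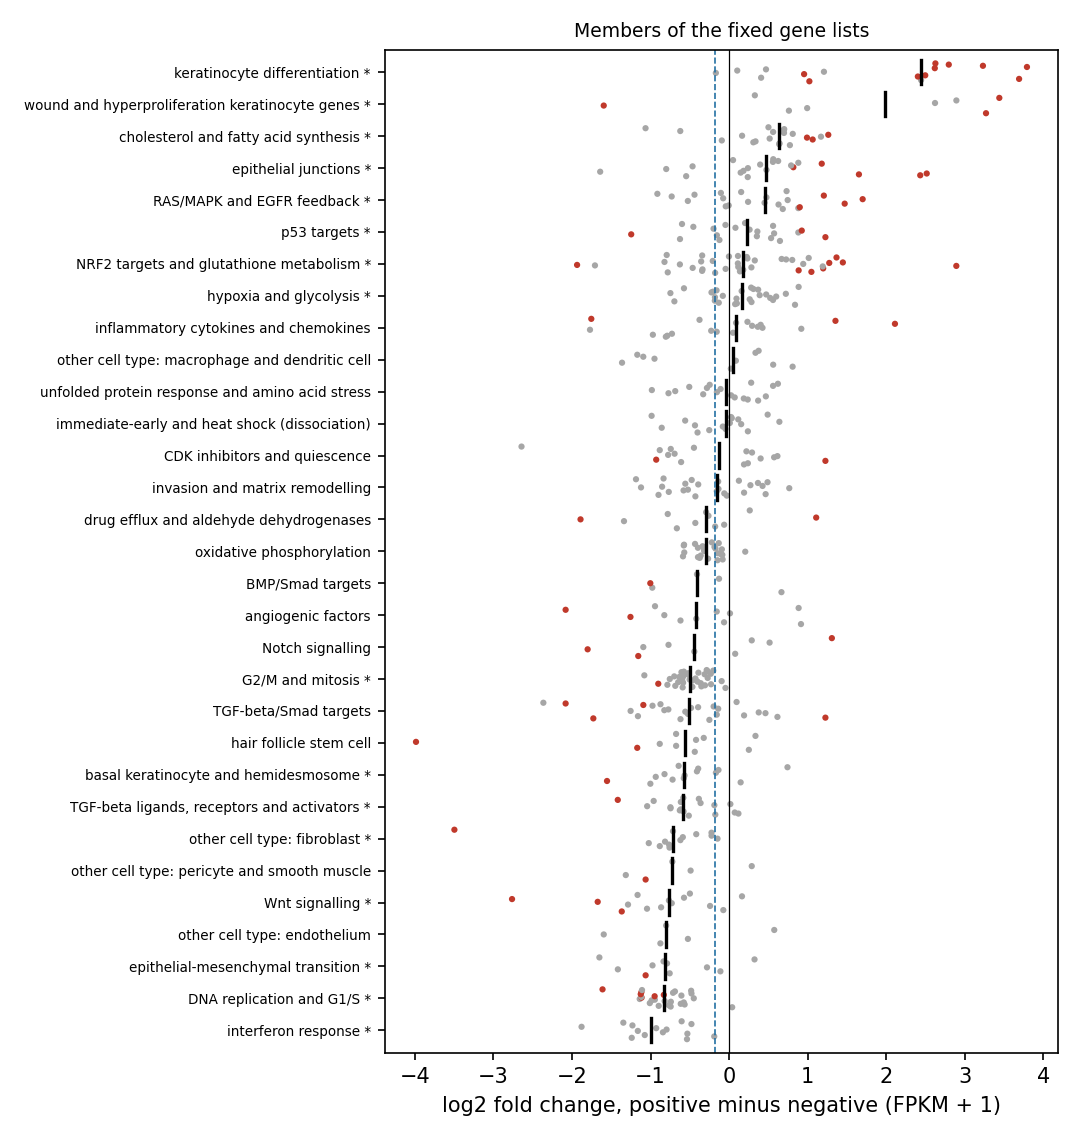
Each point is a member, above 0 in every library, of a list fixed before the data were examined, placed by its log2 fold change (positive minus negative); red points had an adjusted p under 0.05. Black bars are list medians (2.45 for keratinocyte differentiation, -0.83 for DNA replication), the dashed line is the median of all genes tested (-0.18), and asterisks mark the 16 lists with a camera adjusted p under 0.05 at the preset correlation.

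Across the 33 lists tested, 8 were higher and 8 lower at the preset correlation of 0.01, and 0 passed with the correlation estimated from these 4 libraries or with fry. The lowest fry adjusted p of any list was 0.0735. With 2 libraries per group these 2 tests rest on few degrees of freedom, so failing them does not decide for or against a call. At the preset correlation no other list passed. Angiogenic factors had 2 of 11 lower, Thbs1 and the growth factor gene Pdgfa (23.4 ± 5.32 against 9.1 ± 0.931 FPKM), with a median of -0.42 (adjusted p = 0.506). Adjusted over this list alone, 2 were higher and 4 lower, and with blocks 0 and 3. Among 83 cytosolic ribosomal protein genes 0 passed (median -0.07, adjusted p = 0.366). Likewise 0 of 43 histone genes passed (-0.19, 0.954), 0 of 18 stress response genes (-0.04, 0.477) and 0 of 25 invasion genes (-0.16, 0.878). Of the 43 histone genes, 11 were listed at 0 in at least 1 library. Immediate-early and heat shock genes, which respond to tissue dissociation, had a median of -0.05 over 17 members (adjusted p = 0.878). The 1 lower, Jund, was listed at 0 in both reporter positive libraries. With blocks 3 invasion genes, 1 ribosomal protein gene and 2 immediate-early genes were lower, and 1 immediate-early gene was higher. The histone list passed in opposite directions without reporter negative replicate 2 (median -0.395, adjusted p = 0.0143) and without reporter negative replicate 1 (0.025, 0.0203). The ribosomal list passed upward without reporter negative replicate 1 (median 0.088, adjusted p = 7.68e-05) and without reporter positive replicate 2 (0.006, 0.0178). With all 4 libraries and an estimated correlation the adjusted p was 0.987 for histones and 0.951 for ribosomal proteins, and with fry 0.713 and 0.777. Without reporter positive replicate 1 and without positive 2 the invasion median was -0.023 and -0.386 and the stress response median 0.002 and -0.104. The immediate-early median was -0.189 without reporter negative replicate 1 and -0.163 without negative 2. The histone median was -0.378 without reporter positive replicate 1 and 0.016 without positive 2, and the ribosomal median -0.261 without reporter negative replicate 2 and -0.176 without positive 1. Camera put the direction of the ribosomal, stress response, invasion, immediate-early and inhibitor lists up, as it sets them against all genes, while their medians lay below 0. Except for the histones, the medians of these lists from the ribosomal proteins on changed sign with median-of-ratios scaling, to between 0.04 and 0.16.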

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

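The predictions for the tests below were written after the results they measure had been seen, except that for gene length. A part of the signal lay outside every named gene and so entered no comparison: 10.3% and 12.7% of the summed FPKM in the reporter negative libraries of experiments 1 and 2, and 9.9% and 11.7% in the reporter positive ones. Genes that were not analysed here can be among these transcripts.

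The first pattern was genes listed at 0 in both libraries of one fraction and above 0 in both of the other. There were 86 such genes between fractions, against 50 between experiments and 40 for the crossed split, so failures falling at random over libraries were excluded as the whole cause. Failed estimates at loci that carry reads remain a possible cause: 61.6% of the 172 zero values belonged to a gene with a transcript marked as fully covered by reads in the same library, against 80.4% in genes above 0 everywhere and 3.8% in genes at 0 everywhere. Some single genes with this mark had been seen before the count was made. A zero in these files may therefore stand for a gene that was expressed, and whether any of the 86 were silent was not tested.

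The second pattern was the higher level of the differentiation list and the lower level of the replication list, both called at the preset correlation only. One biological explanation, the reporter state itself, was not tested. Gene length was excluded as the whole cause, since after subtracting the median change of genes of like length the medians were 2.65 (1.14 to 3 over resampled members) and -0.66 (-0.81 to -0.52). A few abundant genes taking a larger share were excluded too, with medians under median-of-ratios scaling of 2.61 and -0.63. Reads shared within the Sprr, Lce and Calm families cannot be told apart from a true rise for those families; without them the differentiation median was 1.81 (0.41 to 2.56) over 14 genes, of which 7 rose. A different mix of cells within the sorted fractions, another biological explanation, was not tested either. The gate on integrin α6 and CD44 selects against differentiated cells, but whether it did so equally in both fractions was not tested. Itga6 was at 371 ± 56 against 193 ± 16.9 FPKM without passing (adjusted p = 0.0548, and 0.0156 with blocks).

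The third pattern was the lower level of the TGF-β/Smad targets Thbs1, Tgfbi and Ccn2 and of Thy1 and Postn in the fraction labelled as having TGF-β signalling, although the target Cdkn1a rose and the target list as a whole did not pass (camera adjusted p = 0.205). More fibroblasts in the reporter negative sorts were excluded as the whole source of the summed fall, since Col1a1, Col1a2 and Col3a1 together fell by 12 and 14.9 FPKM in experiments 1 and 2, against 305.1 and 439 FPKM for those 5 genes (3.9% and 3.4%). That sum was carried by Tgfbi (181 and 191.1) and Postn (84.9 and 179.9). Thbs1 (21.1 and 33) and Thy1 (14.7 and 30.7) also each fell by more than the 3 collagens together, and Ccn2 (3.4 and 4.3) by less. The excess over the collagens was small for Thy1 and Thbs1 beside that for Tgfbi and Postn. Fibroblasts therefore stay open as the source for Ccn2, Thy1 and Thbs1, and as a part of the source for Tgfbi and Postn. Other stromal cells as a source were not tested. An exchange of labels in 1 experiment was excluded by the r of 0.524 between the experiments' differences, whereas one in both experiments cannot be told apart from correct labels here, because no reporter transcript is among the annotated genes and the median of the target list, which did not pass, was -0.50. The biological explanation, that cells with an active reporter differ in other ways that lower these genes, was not tested.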

How the results depend on the processing

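Genes listed at 0 left out (alone and with the block), reference transcripts only and transcripts of at least 300 bases were added after the data were seen; every alternative fixed before was run. The 646 genes past the threshold became 1422 with the experiments as blocks, 1002 with robust estimation, 1262 without genes listed at 0 and 3322 with the block as well. It fell to 4 with no filter, 62 with the most abundant transcript, 71 with reference transcripts only and 3 to 191 with 1 library left out, where the lone library was assumed to vary like the other group. A left-out library leaves fewer samples; otherwise the cause was not tested. The other alternatives gave 433 (TPM) to 701 (at least 300 bases). The block ended no call, and among the lists and the genes named in the text it changed no other call than those given, or counted by list, beside the results. Of the 33 lists, 16 passed, 14 to 23 did under other settings (15 to 17 with 1 library left out), and 0 with an estimated correlation or with fry. The Smad target median of -0.50 kept its sign and did not pass in any alternative, and lay between -0.589 (without reporter negative replicate 1) and -0.314 (quantile normalization). The 681 genes 2-fold apart the same way in both experiments became 292 with a pseudocount of 5 and 1836 at 1.5-fold. Over all settings, list results were the same in 601 cases, weaker in 47, stronger in 16 and reversed in 19, and named gene results in 1811, 523, 121 and 12. The reversed list medians belonged to lists that did not pass with all 4 libraries; they were with median-of-ratios scaling invasion 0.039, CDK inhibitors 0.056, immediate-early genes 0.164, unfolded protein response 0.153 and ribosomal proteins 0.148. With quantile normalization they were CDK inhibitors 0.054, immediate-early 0.056 and unfolded protein response 0.111, and with a minimum FPKM of 5 immediate-early 0.01 and macrophage -1.092. With 1 library left out, medians crossed 0 for ribosomal proteins (range -0.261 to 0.088; 0.088 without reporter negative replicate 1, adjusted p = 7.68e-05, and 0.006 without positive 2, adjusted p = 0.0178) and histones (-0.395 to 0.025; 0.025 without negative 1, adjusted p = 0.0203, and 0.016 without positive 2). They did so for CDK inhibitors (-0.322 to 0.073, without negative 2) and the unfolded protein response (-0.104 to 0.002, without positive 1). They also did for inflammatory genes (-0.082 to 0.216; -0.019 without negative 2, -0.082 without positive 2) and macrophage genes (-0.441 to 0.551, negative without positive 2). Reversed genes, none past the threshold, were Cd44 (-0.12 to 0.415 with 1 library left out, -0.081 without negative 1, -0.12 without positive 2), Tgfbr1 (0.642 with the most abundant transcript and with reference transcripts only) and Tgfbr2 (0.661 with the most abundant transcript, -1.234 to 0.07 with 1 left out, 0.07 without negative 2). Others were Hras (0.141 with median-of-ratios, 0.499 with the most abundant transcript and reference transcripts only, -0.197 to 0.048 with 1 left out, 0.048 without positive 2), Hmga2 (-0.023 to 0.405, -0.023 without positive 1) and Vegfa (-1.005 with the most abundant transcript). The cause was not tested. Depth limits what can be seen of low genes: at 1 to 5 FPKM the files' own intervals span 15.5% to 16.9% of the value on each side.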

Other observations

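The genes of this part were chosen for description after their values had been seen. Values follow the order reporter negative 1 and 2, then positive 1 and 2. The T cell gene Cd3e stood at 0.05, 0.021, 0.044 and 0.096 FPKM. The T cell receptor constant gene Trbc2 stood at 70.4, 42.7, 65 and 74.3, all from transcripts placed by overlap, and Trbc1 at 20.1, 13.2, 19.6 and 20. The fatty acid binding protein gene Fabp5, of the sebocyte list, was at 4773, 3331, 9432 and 7780.3 FPKM (adjusted p = 0.118, and 0.0164 with blocks), and Cidea of the same list was listed at 0, 0, 4.31 and 5.04. The globin gene Hbb-bs stood at 20.2, 13.7, 6.46 and 27.4 FPKM.

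Y-linked genes were present in every library: Ddx3y at 11.5, 15.5, 8.3 and 14.5 FPKM and Eif2s3y at 42.3, 43.3, 24.8 and 46.7, with Xist at 0.005, 0.004, 0.034 and 0.734. The 10 most abundant genes held 6.8%, 5.8%, 9.2% and 9.4% of the summed FPKM.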
